A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

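Two-colour Agilent tiling arrays of the Schizosaccharomyces pombe genome were analysed, 1 for each of 2 strains. Per the labels, cells were starved of nitrogen for about 18 h, meiosis was started by adding nitrogen and moving to 34°C, chromatin was sonicated to about 500 to 1000 bp, and Rec12-FLAG was immunoprecipitated without a crosslinker. The immunoprecipitated DNA was amplified by PCR and labelled with Cy5, and whole-cell input was labelled with Cy3, on both arrays, so that no dye was swapped. Strain groups were taken from the sample titles.

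The deposited scanner files hold spot intensity values for both channels. Per the file headers they were made with Agilent Feature Extraction, version 10.1.1.1 for the mbs1-deleted strain and 10.5.1.1 for the mbs1+ strain. Per the file headers the processed intensity of each channel was background-subtracted, corrected for spatial and multiplicative trends and normalized between dyes by a linear factor without a lowess term. The deposited LogRatio column is the log10 of processed red over green signal, per the file headers, and differed from a recalculation by at most 3.8e-07. The authors' value tables hold the same log10 ratios rounded, with a largest gap of 0.005, and medians of -0.0803 and -0.0653. They are Cy5 over Cy3, on a log10 scale and not centred, as their match to the scanner column shows. The software versions and array designs differ between the arrays, so slide, scan and strain cannot be told apart.

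The arrays held 45220 and 45059 spots, of which 42707 and 43832 were genomic probes. Every one of the 42707 was on both arrays, and 1125 probes on the mbs1+ array alone were not used. Probe sequences were matched exactly to assembly ASM294v3, and 42671 matched at a single place, 29 at several and 7 at none. Per the file headers, the array positions of the mbs1+ file refer to an older assembly. The intact positions were equal to ASM294v3 on chromosomes II and III and for 12883 probes of chromosome I but shifted over the rest of it, and one name column of the mbs1+ file gave other positions than the second file for 7475 probes, so all positions come from the sequence match. After removal of 1707 probes with an outlier flag on either array and of probes outside the nuclear chromosomes or without a single match, 40906 remained. No spot was saturated. Median raw signals were 26911 (Cy3) and 11918 (Cy5) on the mbs1-deleted array, against local backgrounds of 30.5 and 137.0, and 22124 and 10761 against 26.0 and 94.0 on the mbs1+ array. The scanner's derivative log ratio SD was 0.225 and 0.320. The number of arrays, 1 per strain, limits the precision.

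The main measure was the log2 ratio of processed Cy5 to Cy3 signal, centred on the median of each array, with no loess or quantile step. Deleted probes were those in the longest run of 3 or more neighbouring chromosome I probes with input lower by 2 or more (log2, median-centred), and their ratio in the mbs1-deleted strain was set aside. A bound on the input there put probes not well above background at the lowest signal among those that were, or at their own if higher. A peak was a stretch of at least 3 probes with a running median over 5 probes of 2 or more, ended by gaps over 1 kb between probes, and peaks under 1 kb apart were merged. Hotspot probes were those in a peak of either strain. Flanks were hotspot probes 5 to 200 kb from the edges of ade6 or of the deleted segment, and reference windows were the same flanks around places 10 kb apart on chromosome II. Windows over all chromosomes were added after the data were seen. They first left out single probes within 600 kb of a locus. Whole windows around places within 600 kb were left out instead once the lowest values had been traced to windows cut short in this way. Both versions are given. Peak overlap needed 1 bp, and chance overlap came from 1000 circular shifts within each chromosome. Centromeres were placed at the longest stretch without a protein-coding gene on each chromosome. A gene's level was the mean over probes within the gene and 500 bp on either side. List percentiles came from 10000 random lists, matched on probe number for level and on level for difference.

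The named genes followed a rule written before the data were examined, as were the main comparisons, 13 gene lists (recombination, meiotic entry, adenine synthesis, markers used in crosses, Atf1 stress response, glucose transport, wtf genes, prl RNAs, ribosomal proteins, histones, Tf2 retrotransposons, transfer RNA genes and flocculins) and most alternatives. The rule took ade6, its neighbours and genes in or beside the deleted segment, the gene at or nearest the summit of the 10 peaks with the largest difference in each direction and of the 10 highest peaks, the 2 highest members and the 2 with the largest difference of each list, and genes in segments found by the input. The flocculin list also held transcription factor genes, among them mbx2, gsf1 and cbf11. Levels of peaks refer to the annotated gene nearest the summit, which need not be the site of breakage. No test between strains was run, because each has 1 array.

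Alternatives were normexp background correction (offset 50, on median signals, because one file holds no mean signals), the uncentred scanner log ratio, loess, quantile normalization, scaling to equal SD on chromosome II, the authors' value tables, a filter on dim probes, removal of a probe GC trend, and other windows, thresholds, smoothing, summaries and overlap rules. The IP channel alone and flanks without the nearest 30 kb were added after the data were seen. The steps were tested on simulated data. With 200 of 402 peaks of the mbs1+ strain changed in a copy with noise of SD 0.5, all changes of 3-fold and 4-fold (68 and 64 peaks) and none of 1.5-fold passed the 2-fold limit, and none of 202 unchanged peaks did. That noise was independent between probes and so averaged out over a peak. On the real arrays, peak differences on chromosome II, where none is labelled, had an SD of 0.55. There 7 of 159 peaks were over 2-fold higher in the mbs1-deleted strain and 4 over 2-fold lower, so the simulation sets no bound on false calls. A shift of 1 downwards planted in 84 flank probes gave a median of -0.93. Of 240 simulated lists without change, 6.25% fell outside the central 95% of percentiles, in a simulation repeated more often after its first draw had been seen. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.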

Results

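Meiotic double-strand breaks were mapped across the fission yeast genome in 2 strains that differ at a pair of break hotspots. Rec12 is the Spo11-type protein that makes the breaks and stays covalently attached to the cut DNA ends, so immunoprecipitation of FLAG-tagged Rec12 without added crosslinker recovers the DNA next to breaks. One strain carries ade6-3049, a hotspot allele of the adenine gene ade6, and has the mbs1 hotspot deleted. The other carries ade6-3057, a control allele without hotspot activity, and has mbs1 intact. Each strain was hybridised once, with the Rec12 immunoprecipitate (IP) in Cy5 against whole-cell input in Cy3, and all differences are given as the mbs1-deleted strain minus the mbs1+ strain. With 1 array per strain, no difference between strains has a replicate check, and SDs below are over the probes of a region. The comparison covered 40906 probes at a median spacing of 270 bp, with 18137 on chromosome I, 14742 on chromosome II and 8027 on chromosome III. Positions refer to assembly ASM294v3.

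The first question was how much Rec12 was linked to DNA at ade6 under each allele. In the ade6-3049 strain, ade6 was among the most strongly bound places in the genome, and in the ade6-3057 strain it was at the genome's median. Over the 13 probes in and within 1 kb of ade6 (chromosome III, gene at 1316281 to 1318035), a phosphoribosylaminoimidazole carboxylase gene of purine synthesis, the log2 IP/input ratio was 6.49 ± 0.93 (SD) with ade6-3049 and -0.03 ± 0.51 with ade6-3057. The difference was 6.52 ± 1.19 (SD over probes), or 91.5-fold. On the 6 probes centred in the gene alone it was 7.06 ± 0.76. The combined scanner error of the difference was 0.70 per probe at the median, which is spot error and leaves out variation between cultures. The hotspot spread over its neighbours. The peak in the ade6-3049 strain ran from 1313018 to 1322664, over 9647 bp and 34 probes, and covered vtc4 and most of bub1. The ratio in bub1, a spindle checkpoint kinase gene, was 3.58 against 0.47, and in vtc4, a gene of vacuolar polyphosphate synthesis, 5.13 against 0.15. The ribosomal protein gene rpl3402 stood at 2.42 against 0.83. By mean ratio the peak ranked 14 of 414 in its strain, and no peak was called at ade6 in the other. The input channel contributed to the size of the ratio: the IP signal at ade6 was 3.98 higher on the log2 scale (15.8-fold) and the difference of the whole-cell input was -2.56.

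The second question was the state of mbs1. The deletion showed in the input as a run of 17 neighbouring probes on chromosome I, from 761164 to 767129, the only run of 3 or more that met the rule. Their median processed input signal was 1.61 in the mbs1-deleted strain and 291.3 in the mbs1+ strain, at least 123-fold lower, and 5 of the 17 were not well above background there. The nearest probes with input in both strains ended at 760826 and began at 767369. The segment takes in part of puf5, a gene for a Pumilio-family RNA-binding protein annotated at 757915 to 761972, all 5 probes of the noncoding RNA gene SPNCRNA.679 and part of SPNCRNA.680, of whose 7 probes 1 kept its input. In the mbs1+ strain these 17 probes carried a mean log2 ratio of 5.37 ± 1.20, a 41.4-fold excess of IP over input, with a highest probe of 7.02. Low input made up part of this ratio: the centred log2 IP signal averaged 2.64 and the input -2.56. The mbs1 peak of that strain spanned 759520 to 768255, and its mean of 4.62 over 26 probes ranked 29 of 402. On the 9 probes of the peak that both strains possess, the ratio was 3.19 ± 0.78 in the mbs1+ strain and 0.39 ± 0.39 in the mbs1-deleted strain, a difference of -2.80 ± 0.64, or 6.96-fold lower. The side toward puf5 differed by -3.06 over 5 probes and the side toward SPAC4G8.04 (767462 to 770246) by -2.47 over 4. With the IP channel alone, an alternative added after the data were seen, the difference was -1.97. Probes inside the deleted segment have no template in the mbs1-deleted strain, and the ratio of 4.77 that the scanner software returns for them there was not used.

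**Figure D1:**
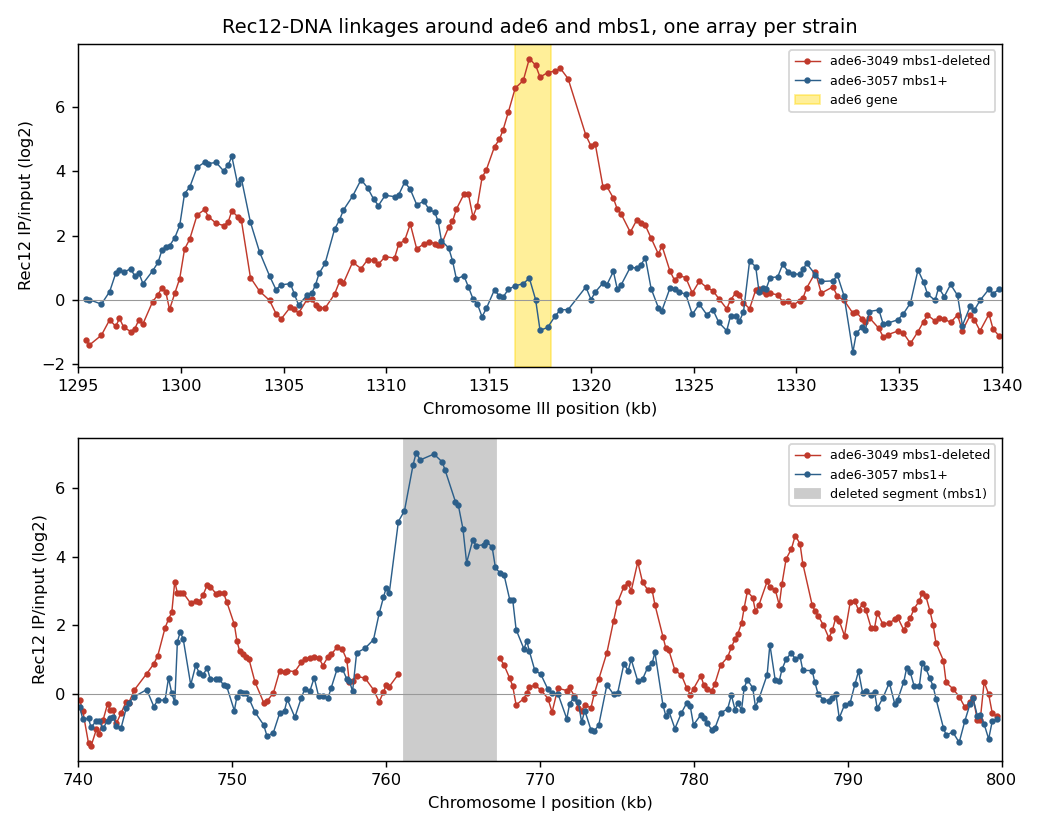
Median-centred log2 ratio of Rec12 IP to whole-cell input (vertical axis) along chromosome III around ade6 (upper panel) and chromosome I around mbs1 (lower panel), position in kb, 1 point per probe, red for the ade6-3049 mbs1-deleted strain and blue for the ade6-3057 mbs1+ strain. At ade6 the red line averages 6.49 and the blue line -0.03, the neighbouring peaks to the left are lower in red, and around the deleted segment in grey, where red has no points, the neighbouring peaks are higher in red.

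The third comparison asked whether hotspots at a distance along the same chromosome differed too, the subject named in the series title. They did so in opposite directions at the loci: hotspots around ade6 were lower in the strain with the ade6 hotspot, and hotspots around mbs1 were higher in the strain without mbs1. Over the 153 hotspot probes 5 to 200 kb from ade6 the median log2 difference was -0.62 (SD over probes 0.85), 1.54-fold lower in the ade6-3049 strain. The sides were unlike, with -1.38 on the left and -0.34 on the right, and the value out to 400 kb was -0.21. Over the 256 hotspot probes 5 to 200 kb from mbs1 it was 1.09 (SD 0.90), 2.13-fold higher in the mbs1-deleted strain, and 0.59 out to 400 kb. Hotspot probes are those in a peak of either strain, so some entered through the strain in which they were high. Over all probes 5 to 200 kb away the medians were smaller, at -0.46 around ade6 and 0.41 around mbs1. The same summary around 410 (ade6 size) and 409 (mbs1 size) places on chromosome II, where no difference between the strains is labelled, had a median of 0.08 and an SD of 0.14, and ranged from -0.32 to 0.39 for the former and from -0.34 to 0.39 for the latter. No chromosome II window was as low as the ade6 flanks or as high as the mbs1 flanks. Neither was any of the 893 and 892 windows of these sizes around places on all 3 chromosomes at least 600 kb from both loci. That set was chosen after the data were seen, and its flanks reached nearer than 600 kb. All places lay at least 200 kb from the chromosome ends, so the right end of chromosome II counted only at the edge of windows. Over the 182 probes of that end the median difference was -0.99, and its lowest 20 kb bin was at -1.90. When windows were instead allowed nearer and only their probes within 600 kb of a locus were left out, 7 of 968 (0.723%) were lower than the ade6 flanks, down to -0.85, with 18 to 25 hotspot probes each, and none was higher than the mbs1 flanks. Neighbouring windows overlap, so these counts describe the arrays and are not a test. The IP channel alone gave -0.27 around ade6 and 0.90 around mbs1, against a mean of 0.32 and an SD of 0.09 over chromosome II windows in that channel.

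The course with distance was uneven around ade6. On its left the median over hotspot probes was -1.91 at 5 to 10 kb, -1.65 at 10 to 20 kb, -0.40 at 20 to 50 kb, -0.28 at 50 to 100 kb, -1.496 at 100 to 200 kb and 0.05 at 200 to 400 kb, each of the first 5 from 7 to 15 probes. The 10 hotspot probes at 100 to 200 kb were those of the peak nearest fah2, and over all 263 probes there the median was -0.47. This stretch runs into the 50 kb beside the centromere of chromosome III. On the right of ade6 there were no hotspot probes within 20 kb. Over all 18 probes 5 to 10 kb to the right the median was higher in the ade6-3049 strain, at 0.63, and over all 35 probes at 10 to 20 kb it was -0.58. The hotspot medians on that side were -1.13 at 20 to 50 kb (3 probes), -0.76 at 50 to 100 kb (44 probes), 0.08 at 100 to 200 kb and -0.14 at 200 to 400 kb. Around mbs1, both sides together, hotspot probes 5 to 10 kb away (8 probes) were higher by 2.40, those at 10 to 20 kb by 2.49, those at 20 to 50 kb by 2.09, those at 50 to 100 kb by 1.14, those at 100 to 200 kb by 0.53 and those at 200 to 400 kb by 0.13. All 7 peaks that lay 5 to 100 kb from ade6 had a lower mean in the ade6-3049 strain, against 37.7% of the 159 peaks on chromosome II, and their median difference was -0.85. Of these, the peak at srk1, a stress-activated protein kinase gene, differed by -1.59 ± 0.23, the peak nearest SPCC338.03C by -1.24 ± 0.38 and the peak of 3 probes nearest ctp1, which encodes a cofactor of break resection, by -1.13. The adjoining peak at knh2, 3718 bp from ade6, differed by -1.70 ± 0.53. On chromosome II, 62.3% of the 159 peaks were higher in the mbs1-deleted strain, 7 of them by over 2-fold. All 7 peaks 5 to 100 kb from mbs1 had a higher mean in the mbs1-deleted strain, with a median of 1.43, and 6 of them by over 2-fold. These included the peaks nearest trm2, a tRNA methyltransferase gene (2.36 ± 0.55), smp3, a gene of glycolipid anchor synthesis (2.32 ± 0.49), ime4, a gene for an RNA methyltransferase homologue (2.22 ± 0.58), and lon1, a mitochondrial protease gene (1.43 ± 0.39). The peaks at smp3 and ime4 stood at mean ratios of 0.28 and 0.56 in the mbs1+ strain and at 2.60 and 2.78 in the other. Those nearest trm2 and lon1 stood at 0.63 and 1.08 against 2.99 and 2.51. All of these averaged below the peak limit of 2 in the mbs1+ strain. Peaks of either strain were counted, so such peaks entered through the strain in which they were high. The counts of direction near both loci are therefore partly fixed by the peak calls. Between 200 and 400 kb the medians over 17 peaks around ade6 and 18 around mbs1 were -0.09 and 0.03. Beyond 400 kb to the right of ade6 a stretch was lower again. Over all probes, the 20 kb bins starting at 1780 to 2000 kb had medians from -0.51 to 0.30, and only the bin at 1820 kb was higher in the ade6-3049 strain.

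**Figure D2:**
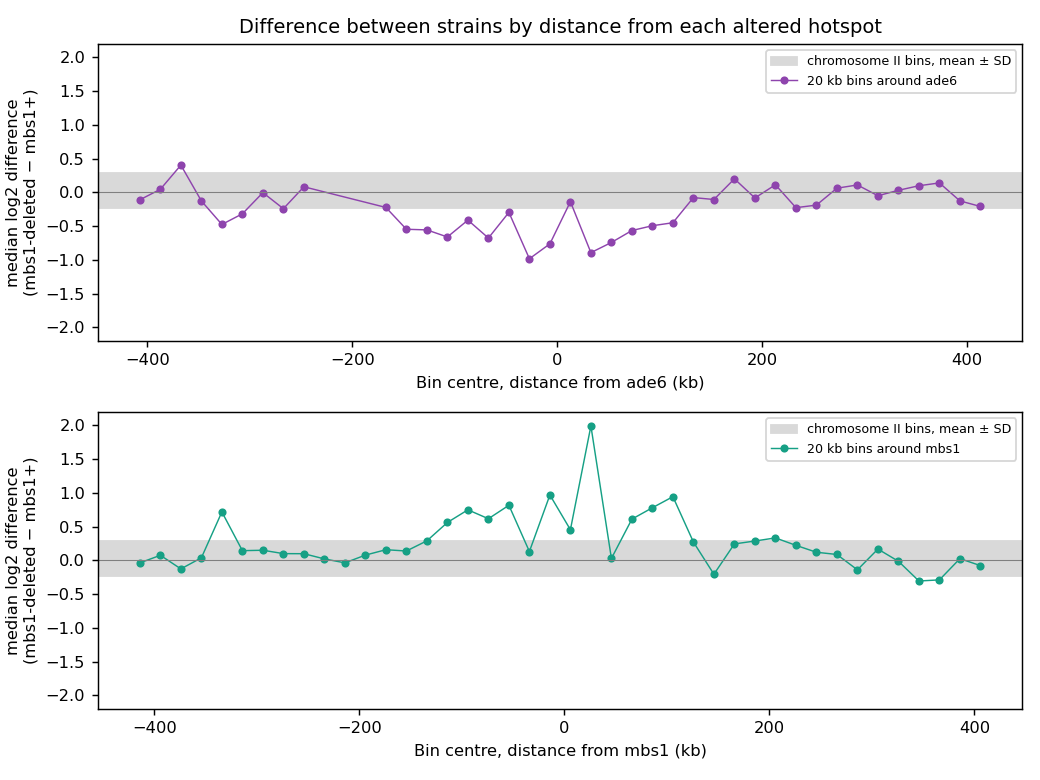
Median log2 difference of the IP/input ratio, mbs1-deleted minus mbs1+, over all probes in 20 kb bins (vertical axis) against distance in kb from the middle of ade6 (upper panel) or of the deleted mbs1 segment (lower panel), with the grey band giving the mean and SD of 223 bins of chromosome II (0.03 ± 0.25). Bins around ade6 lie mostly below the band and bins around mbs1 mostly above it out to about 100 kb. The band does not show the lowest chromosome II bin, at -1.90 near the right end of that chromosome.

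The remaining hotspots of the genome were largely shared. Peaks numbered 414 in the mbs1-deleted strain and 402 in the mbs1+ strain, with median lengths of 3329 and 3222 bp, and held 15.3% and 13.3% of the probes. A peak of the other strain overlapped 85.7% of the former (355 of 414) and 92.3% of the latter (371 of 402). Circular shifts of one set within each chromosome gave 24.5% on average and 39.1% at most over 1000 shifts. Across probes the log2 ratios of the strains had a Pearson's r of 0.926 and a Spearman's rho of 0.851. Across the means of the 445 peaks called in either strain, Pearson's r was lower, at 0.759. Neighbouring probes are not independent and no p-value is attached. The 10 hotspots with the highest mean over both strains lay nearest hsr1, SPAPB15E9.06, fhn1, pdc201, spo14, ste11, SPBC609.01, rtn1, SPBC713.14C and mug115, with means from 5.23 at hsr1 to 4.57 at mug115. Their differences between strains ran from -0.68 at fhn1, an eisosome gene, to 0.00 at spo14, and none reached 2-fold. At ste11, whose product is the transcription factor for mating and entry into meiosis, the mean was 4.71 and the difference -0.18.

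Of the 445 peaks in the union of both sets, 405 (91.0%) differed by less than 2-fold, 29 were over 2-fold higher in the mbs1-deleted strain and 11 over 2-fold lower. Beyond 100 kb from both loci, 22 of 428 peaks were over 2-fold higher and 6 over 2-fold lower. The largest difference upward outside the loci was at pma2, a plasma membrane proton pump gene (chromosome III, 790537 to 794395), at 1.63 ± 0.48. It was followed by SPAC13C5.04 (1.48), rad55, a gene of recombinational repair (1.44), ppr7 (1.43) and ctr4, a copper transporter gene (1.41). The largest downward outside the loci was nearest isp4, an oligopeptide transporter gene (chromosome II, 1552641 to 1557022), at -2.16 ± 0.28. It was followed by SPBPB2B2.06C (4469672 to 4473794, -2.14 ± 0.24) and SPBPB2B2.05 (4465242 to 4467511, -1.94 ± 0.36), which lie near the right end of chromosome II. Next were the peak nearest fah2, 117375 bp from ade6, at -1.42 ± 0.34, and say1 (4459711 to 4461457, -1.17 ± 0.38) at the same end of chromosome II. The split between directions depended on scaling. Quantile normalization between the arrays gave 24 higher and 15 lower, and loess within each array gave 46 higher and 52 lower.

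**Figure D3:**
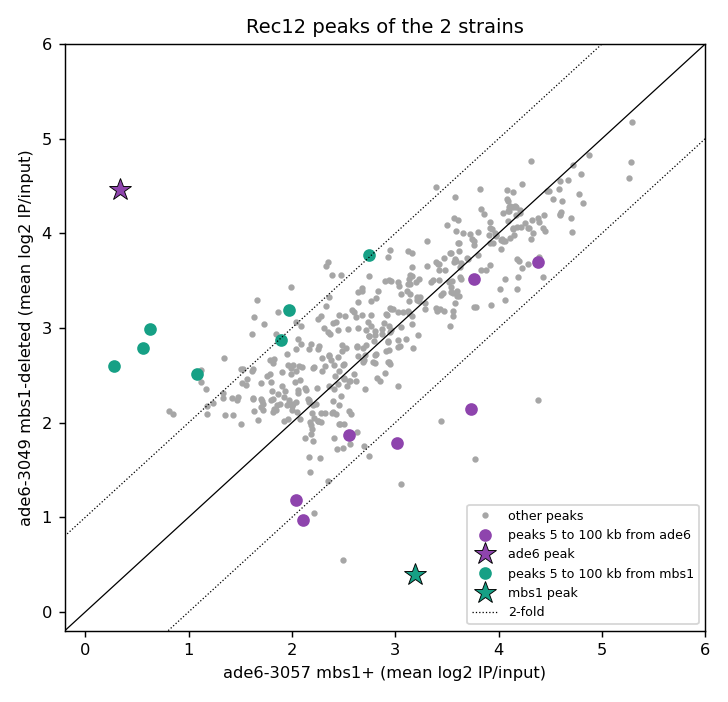
Mean log2 IP/input ratio of each of the 445 union peaks in the ade6-3057 mbs1+ strain (horizontal axis) and the ade6-3049 mbs1-deleted strain (vertical axis), with the line of equality and dotted lines at 2-fold. The ade6 peak (4.46 against 0.33) and the mbs1 peak outside the deletion (0.39 against 3.19) stand at opposite corners, the 7 peaks 5 to 100 kb from mbs1 lie above the line and the 7 peaks 5 to 100 kb from ade6 below it.

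Breaks favoured the spaces between protein-coding genes in both strains. These spaces can hold noncoding RNA genes, which were not set apart. The median log2 ratio of the 8641 probes between coding genes exceeded that of the 32150 probes in protein-coding genes by 1.07 in the mbs1-deleted strain (2.09-fold) and by 0.71 in the mbs1+ strain (1.64-fold). Peaks held 29.6% and 26.0% of the probes between coding genes, and 11.5% and 9.89% of those inside them. Within 50 kb of the centromeres the median ratio was -0.66 in the mbs1-deleted strain and -0.40 in the mbs1+ strain, but the centromeres were unlike. Chromosome I had -0.82 and -0.61 there and chromosome III -0.77 and -0.44, whereas chromosome II, at -0.07 and 0.04, lay near the genome's median. The chromosome III part ran to 1192385 and so shared probes with the left flank of ade6. The outer 100 kb of the chromosomes had medians of -0.06 and 0.00, against 0.02 and 0.01 in the rest of the genome. These values depended on the distance taken, with -1.03 and -0.77 in the outer 50 kb and 0.33 and 0.19 in the outer 200 kb, and the 6 ends differed from one another.

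Among the 13 gene lists fixed before the data were examined, several had a high median level against random lists matched on probe number. Those random lists were not matched on chromosome or on the width of the spaces beside genes. A high percentile is therefore not shown to be particular to a list. In every list but glucose transport (5 of 8), a minority of genes stood at 4-fold or more. The transfer RNA genes were the list whose median difference lay outside all random lists matched on level alone. The median differences of the other 12 lists ran from -0.06 for meiotic entry to 0.30 for histones, at percentiles of 4.40 to 95.03. These are medians of differences gene by gene, and for 5 of the lists the medians of the strains differed the other way: 1.23 in the mbs1-deleted strain and 1.80 in the mbs1+ strain for histones, 0.75 and 0.59 for meiotic entry, 2.19 and 2.12 for glucose transport, 1.36 and 1.39 for wtf genes and 0.02 and 0.08 for markers used in crosses. Genes for glucose transport had the highest level, with a median log2 ratio of 2.15 over 8 genes (percentile 99.9 among random lists matched on probe number), led by ght4 at 3.49 and ght1 at 2.95. The largest differences in that list were 0.27 at ght3 and -0.23 at ght2. The histone list had a median of 1.51 over 10 genes (98.5), with hhf3 at 5.07 and hhf2 at 3.79, and its largest differences were at the neighbours htb1 (-0.90) and hta1 (-0.82), which lie under 100 kb from ade6. The Atf1 stress response list had 1.47 over 22 genes (99.98), with 9 genes at 4-fold or more, among them the heat shock gene hsp16 at 5.04 and gst2 at 4.07. Its differences were largest at cgs2 (-0.95) and grx1 (0.77). The wtf spore killer genes had 1.40 over 23 measured genes (99.6), led by wtf25 at 4.25 and wtf11 at 3.73. The largest differences were at wtf5 (0.58) and wtf11 (-0.57), the latter under 100 kb from ade6. The flocculin list, which also holds transcription factor genes, had 1.26 over 12 genes (99.8). It was led by the transcription factor genes mbx2 at 4.74 and gsf1 at 3.93. Its largest differences were 0.56 at pfl4 and 0.46 at cbf11, the latter also a transcription factor gene. The polyadenylated prl RNAs had 0.84 over 57 genes (99.7), led by prl35 at 5.44 and prl3 at 5.16, with the largest differences at prl40 and prl65 (both 1.39). The meiotic entry list had 0.67 over 17 genes (98.1), led by ste7 at 4.06 and ste11 at 3.96, with differences of -0.56 at map2 and -0.44 at ste6.

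The other lists lay nearer to the random lists. Transfer RNA genes had a median of 0.40 over 131 genes (94.2), with scn1 at 5.82 and SPCTRNAGLN.06 at 5.68, and the median difference of 0.34 lay above all random lists matched on level, whose median was 0.10. Those lists were not matched on lying between coding genes, where the probes as a whole had medians of 0.89 in the mbs1-deleted strain and 0.61 in the mbs1+ strain. The difference is therefore not shown to be particular to transfer RNA genes. Their largest differences were 1.62 at SPATRNAGLU.01, which lies under 100 kb from the deleted mbs1 segment, and 1.59 at SPATRNAVAL.01. Only 4 of these short genes have a probe centred in them, so the values come mainly from the 500 bp on either side. Ribosomal protein genes had 0.35 over 131 genes (92.0), led by rps1102 at 4.57 and rpl1202 at 4.03, with the largest differences at rpl3402 (1.69) and rpl2302 (-0.95), both beside ade6. Tf2 retrotransposons had 0.88 over 9 measured elements (81.3), with Tf2-3 at 1.87 and Tf2-12 at 1.30 and differences of 0.99 at Tf2-9 and -0.73 at Tf2-2, each from 1 probe beside the element. Recombination genes had -0.09 over 26 genes (44.5). Within that list rec12 itself lay in a strong hotspot, at 5.57 in the mbs1-deleted strain and 5.79 in the mbs1+ strain, and rec7 had 3.13. The largest differences were at ctp1 (-1.21), under 100 kb from ade6, and mre11 (0.73). Markers used in crosses had -0.03 over 32 genes (51.2), led by lys4 at 3.01 and his5 at 2.27, with differences of 0.87 at ura4 and 0.80 at lys3. Adenine synthesis genes had -0.19 over 10 genes (39.2). Apart from ade6, the member with both the highest level and the largest difference was ade7, at 0.85 and 0.68.

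The input channel was also searched for sequence that one strain lacks. At a mean difference of 2 on the log2 scale over 3 probes, 7 segments were found, and 2 of these were lower in the mbs1-deleted strain. One was the mbs1 deletion, which overlaps puf5. The other covered ade6 and 14 probes from 1315491 to 1320016 with a mean input difference of -2.54 ± 0.74, while the IP signal over the same probes was higher by 3.90. The 5 segments higher in the mbs1-deleted strain held 3 to 5 probes each, lay at or nearest SPAPB24D3.07C, SPAC17A2.11, wsp1, lsd90 and ght6, and had higher IP signals too, by 1.06 to 2.72. Their mean input differences were 1.94 to 2.44, with uneven probes (SDs of 0.92 to 2.85). At SPAC17A2.11 the SD of 2.85 exceeded the mean of 2.18.

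**Figure D4:**
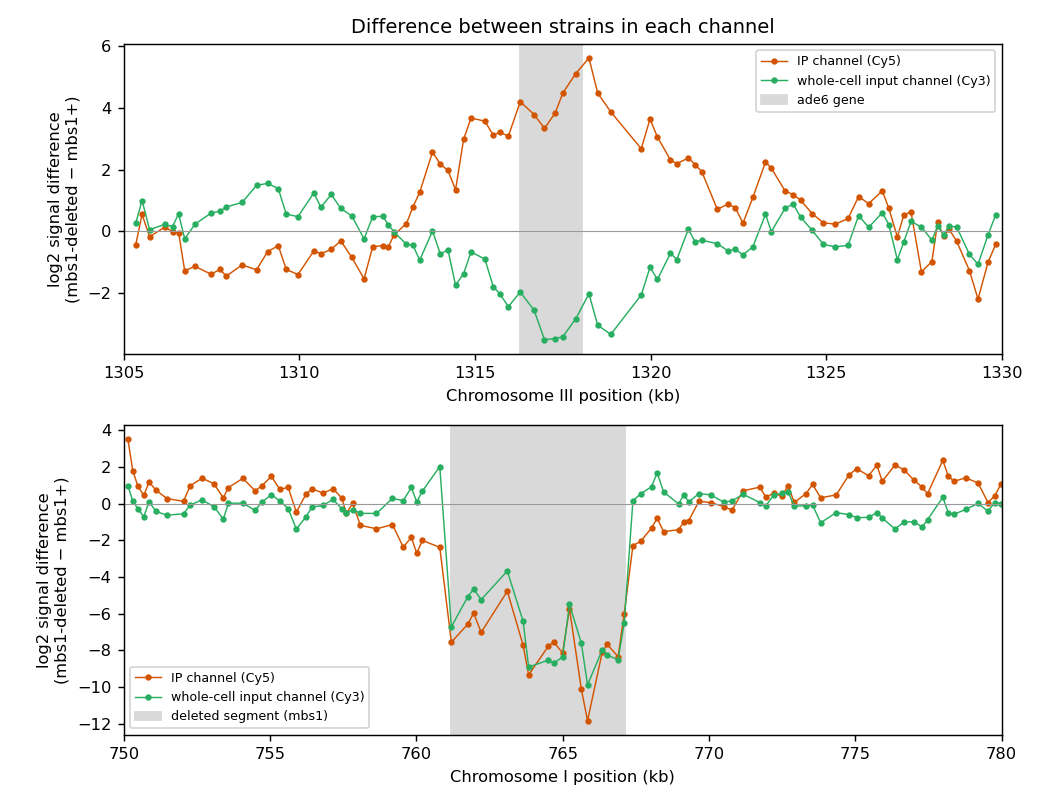
Log2 signal difference between strains, mbs1-deleted minus mbs1+, of the Rec12 IP channel (orange) and of the whole-cell input channel (green), each centred on its array's median, along chromosome III around ade6 (upper panel) and chromosome I around mbs1 (lower panel), position in kb, 1 point per probe. Over the deleted segment both channels are far lower, the input at least 123-fold with 5 of the 17 probes not well above background, whereas over ade6 the IP is higher (3.98) and the input lower (-2.56).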

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

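The directions at ade6, at mbs1 and in the flanks of both loci were the same under every alternative run, and 149 of the 202 recomputed values that an alternative changed at all stayed within the spread set for them (SD over probes at the loci, SD of chromosome II windows for flanks, 1.5 times for counts, the 95% interval for overlaps, resampled 100 kb blocks for correlations and gene spacing, SD of random lists for gene lists). For chromosome regions the spread was the SD between ends, between centromeres or between chromosomes. It reached 0.97 for the ends of the mbs1-deleted strain, so that their move from -0.06 to 0.33 in the outer 200 kb counted as within it. A further 11 values came out equal to the main ones, some because a shift or rescaling of a whole array cannot change them. The filter on dim input and saturated probes left all of its 13 values as they were. Probes of the deleted segment were exempt from it and no other probe failed it. It therefore removed nothing and says nothing about stability. The IP channel alone and the flanks without 30 kb were chosen after seeing the data. Where values moved, the cause was not tested, except that stricter thresholds pass fewer peaks.

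The ade6 difference left its spread only with the IP channel alone, at 3.98. That spread of 1.19 is an SD over probes and does not measure the effect of processing. Within it, the difference was 5.62 with normexp, 5.87 with loess and 5.88 for probes within 2 kb. It was 6.61 with quantile normalization and 7.06 for the gene alone. The mbs1 difference moved to -3.97 for the highest single probe and to -1.97 for the IP channel alone. The ade6 flanks were -1.65 at 5 to 50 kb, -0.93 at 5 to 100 kb, -0.21 at 5 to 400 kb, -1.38 on the left and -0.34 on the right, -0.46 over all probes, -0.83 from summed linear excess, -0.85 at a peak threshold of 2.5, -0.78 with loess, -0.81 with quantile normalization, -0.43 without the nearest 30 kb and -0.27 for the IP channel alone. The mbs1 flanks were 2.33 at 5 to 50 kb, 1.72 at 5 to 100 kb, 0.59 at 5 to 400 kb, 0.41 over all probes, 0.86 from summed linear excess, 0.84 with loess, 0.91 with quantile normalization, 0.79 without the nearest 30 kb and 0.90 for the IP channel alone. Flank values of the IP channel alone are to be read against that channel's chromosome II windows, whose mean was 0.32.

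Peak numbers stayed within 1.5 times under the alternatives run. The overlap for the mbs1-deleted strain was 73.4% with loess, 90.2% with quantile normalization and 79.0% for summits within 1 kb, and for the mbs1+ strain 87.9% with quantile normalization, 95.1% at a peak threshold of 1.5 and 81.3% for summits within 1 kb. The correlation was 0.896 with normexp, 0.867 with loess, 0.851 as Spearman's rho, 0.841 over hotspot probes alone and 0.947 in bins of 1 kb. Peaks higher and lower in the mbs1-deleted strain numbered 46 and 52 with loess, 91 and 35 at 1.5-fold, and 5 and 6 at 3-fold. The excess between coding genes was 0.84 in the mbs1+ strain with loess and 0.98 and 0.78 (mbs1-deleted, mbs1+) with quantile normalization. Input segments numbered 33 at a difference of 1.5 and 4 at 3. The outer 50 kb of the chromosomes had medians of -1.03 in the mbs1-deleted strain and -0.77 in the mbs1+ strain. With gene bodies alone, transfer RNA genes, of which 4 were then measured, had a level of -0.52, below 0, and a difference of 0.54, and ribosomal protein genes a difference of 0.11. Tf2 elements then had no probe and gave no value. With normexp the transfer RNA level was 0.23, the ribosomal protein difference 0.094 and the prl RNA difference 0.23. Signal over background limited the input reading at 5 probes, all of them in the deleted segment.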

Other observations

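The tests of hotspot strength, of the input channel in the flanks, of distance, of the IP and input signals over ade6 and of the chromosome II end were chosen only after the result they measure, or one close to it, was seen.

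Rec12 binding was higher in wide than in narrow spaces between coding genes, though not at every step of width. In the mbs1+ strain 5.88% of 1412 spaces under 500 bp touched a peak, 30.4% of 570 spaces of 1000 to 2000 bp, 56.3% of 158 spaces of 2000 to 3000 bp, 52.1% of 71 spaces of 3000 to 5000 bp and 88.9% of 18 spaces of 5000 bp or more, with median log2 ratios of -0.19, 0.91, 1.80, 1.70 and 3.67. The mbs1-deleted strain had 9.21%, 34.6%, 57.6%, 52.1% and 83.3% for the same widths. A wider space has more bases that can touch a peak, so these shares rise with width in part by construction. The median ratios do not depend on touching a peak. Chromosome III held the most peaks per Mb in both strains, 36.7 and 40.8 in the mbs1-deleted and mbs1+ strains, against 31.0 and 29.4 on chromosome I and 33.3 and 30.4 on chromosome II. Of the chromosome ends, the left end of chromosome I (1.43 and 1.35) and the left (1.05 and 0.64) and right (0.48 and 0.22) ends of chromosome III had median ratios above the genome's in both strains, and the right end of chromosome I (-1.06 and -0.82) and the left end of chromosome II (-1.08 and -0.89) lay below it. The right end of chromosome II had -0.15 and 0.89. The highest probe of either array, at 7.91 and 8.17, exceeded the highest at ade6 (7.51) and at mbs1 (7.02).

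Hotspots near ade6 were lower, and hotspots near mbs1 higher, in the mbs1-deleted strain. A difference between the arrays tied to hotspot strength is argued against by chromosome II hotspot probes of matched mean level, whose median differences were 0.18 for the match to either locus. A difference in the whole-cell input alone is argued against by the IP channel, with medians of -0.27 around ade6 and 0.90 around mbs1 against a mean of 0.32 and an SD of 0.09 over chromosome II windows, though the input added to the ratio on both sides. A hypothesis, formed on these data and without an independent test in them, is that an active hotspot may lower breakage at hotspots near it. The rank correlation of peak difference with distance restates the pattern that prompted it and decides nothing: it was positive around ade6 between 5 and 400 kb (Spearman's rho 0.60 over 30 peaks, 0.83 left and 0.51 right) and negative around mbs1 (rho -0.73 over 30 peaks, -0.61 left and -0.74 right). Each locus was changed in 1 strain pair with 1 array per strain, so other differences between the strains or slides remain untested.

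Whole-cell input over ade6 was lower in the strain with the ade6 hotspot, at a centred log2 value of -2.41 against 0.15. Sequence missing from the strain, or not matching the probes, is argued against by the IP signal on the same probes, which was 3.98 higher (SD 0.78). A fall of input signal wherever the IP is bright, as an array effect or as loss of Rec12-bound DNA from the input, stays open. Chromosome II probes with IP signals in the range of the ade6 probes had a mean input of -0.89 (SD 0.88, 621 probes) on the same array and of -1.29 (SD 1.03, 437 probes) on the mbs1+ array, less low than ade6. Single stretches of 13 chromosome II probes with a mean IP in that range were as low as ade6, however, 6 of 328 overlapping stretches on the same array (lowest -2.63) and 23 of 170 on the mbs1+ array (lowest -3.02), and the mbs1 segment had -2.56 in the mbs1+ strain.

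The right end of chromosome II had a median difference of -0.99 over its 182 probes, with the 4 peaks there between -2.14 and -0.16. Sequence of that end lost from, or diverged in, the mbs1-deleted strain is argued against by the input over those peaks, which was higher by 0.44 on average. A difference of all chromosome ends is argued against by the other 5, whose medians ran from -0.18 to 0.43. Neither altered hotspot lies on chromosome II, so the design names no biological explanation and none was tested.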
